A study of Drosophila melanogaster with 2 samples.

How the data were processed

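Chromatin from 0 to 24 h embryos of mixed sex was immunoprecipitated with an anti-GFP antibody and sequenced in 2 biological replicates of 1 group, labelled 2 and 3. Per the labels, the animals were transgenic and expressed Su(var)2-10 with a C-terminal GFP tag. Fragments were made by sonication at 200 to 800 bp, also per the labels. Read counts, alignments and control profiles were not used here, so the depth per sample is unknown.

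For each build, dm6 and dm3, the authors deposited a list of peaks and background for each replicate, such a list for the pooled replicates, and a list of peaks past an IDR threshold. The replicate lists were called per replicate against a control and the pooled list from the pooled alignments, per the submitters' file notes deposited with each sample. The aligner, the peak caller, the IDR version and its threshold are not given in the sources used here. The signal value of each peak is a score the authors deposited with no fixed unit, so it was compared only within a list. The deposited −log10 q of each peak gave its q-value, and the deposited summit offset its position. The dm6 candidate lists held 30000 peaks each, and reproducible peaks were the 2942 peaks past the threshold on dm6. Peaks of the pooled list that did not pass numbered 27058. Some neighbouring peaks overlap, so the 2942 peaks form 2536 regions and are not fully independent.

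Annotation came from Ensembl release 115 (BDGP6.54) and sequence from the RefSeq Release 6 assembly, which is dm6. Arm lengths were compared with the highest peak ends before use. No dm3 reference was used, and no coordinate was converted. Gene symbols in the lists were matched to the annotation directly or through synonyms in the RefSeq annotation. The names calypso, Dl, nos and rye found no match and were left out.

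Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Replicate agreement was the share of summits within 100 bp of a summit in the other replicate, among as many best peaks as the reproducible set holds, against 1000 circular shifts within chromosome arms (one-sided). A promoter peak had its summit within 250 bp of any annotated start site. Other summits were assigned in the order 5' UTR, coding sequence, 3' UTR, intron, other exon and intergenic. Shares were compared with shifts (two-sided) and with candidate peaks by Fisher's exact test (two-sided). Peaks per region were compared with non-N sequence length by an exact binomial test. Pericentric heterochromatin was set by hand as 2L from 22 Mb, 2R to 5.7 Mb, 3L from 22.9 Mb, 3R to 4.2 Mb and X from 22.4 Mb. Gene lists were tested by Fisher's exact test, counting a gene when a reproducible summit lay within 500 bp of a start site, over 13945 protein-coding genes outside Y. Non-coding genes were counted within 250 bp of the gene body. Motifs were searched as exact consensus matches on both strands in 200 bp around the summit, with windows centred 500 bp to each side as control. Summit and flank windows of the same peak were tested as independent, so pairing within a peak was not used. Medians of signal were compared with 100000 permutations. P-values were adjusted by the Benjamini-Hochberg method within each family (8 regions, 31 gene lists, 6 non-coding classes, 17 motifs, 7 locations), with a threshold of 0.05, and intervals are 95% Wilson or Clopper-Pearson intervals.

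The 31 lists, the motifs, the tests and the main alternatives were set before the data were examined. The 31 lists covered SUMO, H3K9 methylation and HP1, piRNA, JAK/STAT, Polycomb, trithorax, deacetylase, insulator, homeotic, segmentation, developmental signalling and ecdysone genes, ribosomal proteins of cytoplasm and mitochondria, proteasome, translation, oxidative phosphorylation, cell cycle, histone, heat-shock, dosage compensation, telomere, chemoreceptor, cuticle and antimicrobial peptide genes, and markers of neurons, muscle, hemocytes and fat body, midgut, germline and testis. Genes were named by a rule set at the same time. It took the protein-coding gene with the nearest start site at each of the 25 strongest peaks within 500 bp of one, the 5 strongest peaks with no start site that near, and up to 4 members with a peak for lists past the threshold or 2 for the others, by signal. Su(var)2-10 and all members of the SUMO, H3K9 and piRNA lists with a peak were named as well. A gene that this rule takes is not reported here.

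Alternatives covered other distances, the 1471 reproducible peaks with the highest signal, the best 2942 peaks of either replicate alone, other backgrounds and controls, other start-site rules, moved heterochromatin boundaries and the dm3 build. Replicate overlap by interval required at least 50% of both peaks and used 100 shifts. Alternatives added after seeing the data were 1 summit per group of overlapping peaks, GC-matched motif controls, rotation of list membership along the gene order by all 13944 offsets, annotated transposable elements, regions compared with candidate peaks, and arms without their pericentric parts.

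The functions were tested on simulated data. With 35.3% of 2942 simulated summits at start sites the promoter share came out as 35.5%, and with 60.0% of summits shared the replicate agreement came out as 60.3%. All 9 lists with at least 30 members were recovered when peaks were placed at 50% of their members, 8 of them by rotation too, and 0 of 620 list tests passed with random genes. A motif written into simulated windows gave 20.8% where 20.6% was made, and 0 of the 15 unrelated motifs passed. For the 8-base search, 20 of 20 sequences written into 5.00% of simulated windows led the search and passed on the arms held out, and with none written in, 1 of 20 leading sequences passed there. Simulated summits and controls lay at random positions, without the differences in promoter share and GC content of the real lists. The rates for motifs and 8-base sequences do not cover calls that such differences bring. Random genes were drawn independently of each other, so the rate for gene lists does not cover neighbouring genes that share a peak.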

Results

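Su(var)2-10 is the PIAS-family SUMO E3 ligase of Drosophila melanogaster, a protein that directs the attachment of the small modifier SUMO to other proteins. Its gene was found as a suppressor of position-effect variegation, the patchy silencing of genes that lie next to heterochromatin. The series mapped where the protein sits on chromatin by chromatin immunoprecipitation and sequencing with an antibody to GFP. It used whole embryos of mixed sex aged 0 to 24 h from a transgenic line carrying Su(var)2-10 with GFP at its C-terminus. The samples formed 1 group of 2 biological replicates, labelled 2 and 3, with chromatin sonicated to 200 to 800 bp. No second genotype, tag or stage was compared, so the comparisons were between replicates, between reproducible and other peaks, and between peaks and the annotated genome. The lists hold peaks and not reads, so the depth behind them is unknown and intervals cover counting error only.

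On the dm6 build each replicate had a list of 30000 candidate peaks, and so had the pooled replicates. These lists hold peaks and background, so candidate peaks include regions at background level. The lowest −log10 q was 0.109 in the pooled list, 0.107 in replicate 2 and 0.132 in replicate 3, against 1.58 among the peaks past the filter. The list of peaks that passed the authors' irreproducible discovery rate (IDR) filter held 2942 peaks, called reproducible peaks from here on. They merged into 2536 regions that covered 1.38 Mb. The signal value of a peak is the authors' own score and is used here only to rank peaks within a list. It ran from 129 to 2409 over the reproducible peaks, with a median of 195. The reproducible set was identical to the 2942 highest-signal peaks of the pooled list, and its weakest peak had a q-value of 0.0263. Comparisons of reproducible with other peaks of that list are therefore comparisons of higher with lower pooled signal.

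Both replicates placed most of their strongest peaks at the same positions. Of the 2942 best peaks of replicate 2, 60.4% (95% Wilson interval 58.6 to 62.2) had a summit within 100 bp of a summit among the 2942 best of replicate 3, and 60.4% of the best of replicate 3 were matched in replicate 2. Circular shifts of the summits within chromosome arms matched 0.435% ± 0.126 (SD over 1000 shifts; one-sided permutation p = 0.000999, the smallest the shifts can give). Matching fell from 76% among the 100 best to 33.7% when all 30000 candidate peaks of each replicate were used, where shifts matched 4.58%. Across the 1777 matched best peaks, signal ranks correlated with a Spearman's rho of 0.713, a value across peaks, which are not independent replicates. The 3 peaks of highest signal were intronic peaks in CG11050, ush and Trl, with ranks 1, 2 and 3 in replicate 2 and 1, 2 and 5 in replicate 3. Of the reproducible peaks, 88.9% had a summit within 100 bp in both full replicate lists, and 60.5% were among the best 2942 of both. The share among the best 2942 of neither replicate was 4.25%, or 125 peaks. For 16 reproducible peaks neither full list had a summit within 100 bp.

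**Figure D1:**
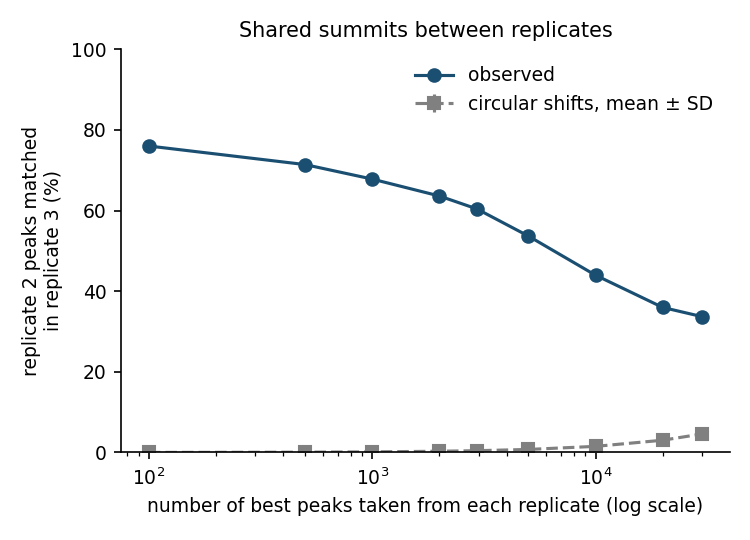
Share of replicate 2 peaks (%, y axis) with a replicate 3 summit within 100 bp, against the number of best peaks taken from each replicate (log scale). Circles are the observed shares, which fall from 76% at 100 peaks to 33.7% at 30000, and squares are the mean ± SD of 100 circular shifts, 4.58% at 30000.

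Su(var)2-10-GFP peaks were in excess at promoters and nearly absent from protein-coding sequence, while introns held about the share that shifted summits had. Of the 2942 reproducible peaks, 1089 had a summit within 250 bp of an annotated transcription start site, which is 37.0% (95% Wilson interval 35.3 to 38.8). Introns held 1197 (40.7%), intergenic sequence 525 (17.8%), other exons 52 (1.77%), 5' UTRs 42 (1.43%), 3' UTRs 31 (1.05%) and coding sequence 6 (0.204%). Circularly shifted summits fell at promoters in 7.51% ± 0.567 (SD), in introns in 41.0% ± 1.34 and in coding sequence in 15.5% ± 0.919, and the promoter share exceeded every shift (two-sided permutation p = 0.002, the smallest the shifts can give). Candidate peaks of the pooled list that did not pass the filter were at promoters in 3103 of 27058 cases (11.5%) and in coding sequence in 8.63%. The odds of a promoter position were 4.54 times higher for reproducible peaks (two-sided Fisher's exact p = 1.35e-244). For 3' UTRs the odds ratio was 0.124 (Fisher's exact test, adjusted p = 1.22e-60 over 7 locations) and for introns 0.736 (adjusted p = 8.94e-15). Along the pooled list the promoter share went from 48% at ranks 1 to 100 through 30.7% at ranks 2001 to 2942 to 8.23% at ranks 20001 to 30000.

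**Figure D2:**
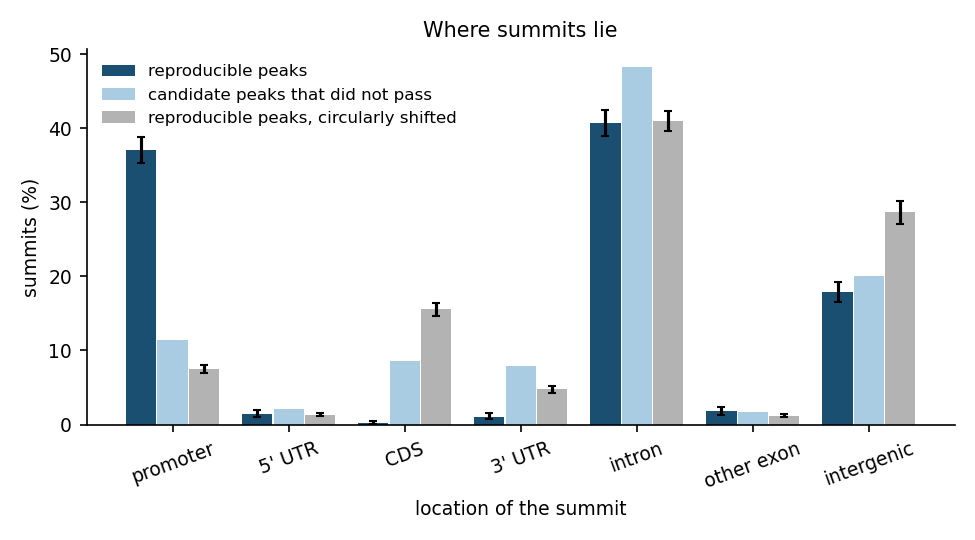
Share of summits (%, y axis) by annotated location for the 2942 reproducible peaks (dark, with 95% Wilson intervals), the 27058 candidate peaks that did not pass (light) and the reproducible peaks after circular shifts (grey, mean ± SD of 1000). Promoters held 37.0% of reproducible peaks, 11.5% of candidate peaks and 7.51% of shifted summits, and coding sequence held 0.204%, 8.63% and 15.5%.

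At promoters the summits lay upstream of the start site. Among the 1089 promoter peaks, 916 (84.1%, 95% Wilson interval 81.8 to 86.2) had the summit upstream of the nearest start site, with a median offset of -119 bp and quartiles of -176 and -55 bp. The promoter peaks that did not pass were upstream in 59.9% of cases, with a median offset of -44 bp (odds ratio 3.54, two-sided Fisher's exact p = 6.73e-52). This comparison was chosen after the positions had been seen. The side was taken from the nearest start site of either strand, so a summit between start sites that point away from each other counts as upstream. Start sites of both strands lay within 500 bp at 52.7% of reproducible and 29.7% of candidate promoter peaks. How far this accounts for the difference in side was not tested. Promoter peaks also had a higher signal than the other reproducible peaks, with medians of 206 (1089 peaks) and 185 (1853 peaks), a difference of 21.0 (two-sided permutation p = 2.0e-05, the smallest that 100000 resamples can give). Among the 1471 reproducible peaks with the highest signal the difference was 0.0768 and did not pass (permutation p = 1). That subset was itself chosen by signal, so its value says little about the whole set. In the lists of replicate 3 alone and replicate 2 alone, whose scores run lower, the difference was 9.03 and 12.5 and passed in both (permutation p = 2.0e-05).

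**Figure D3:**
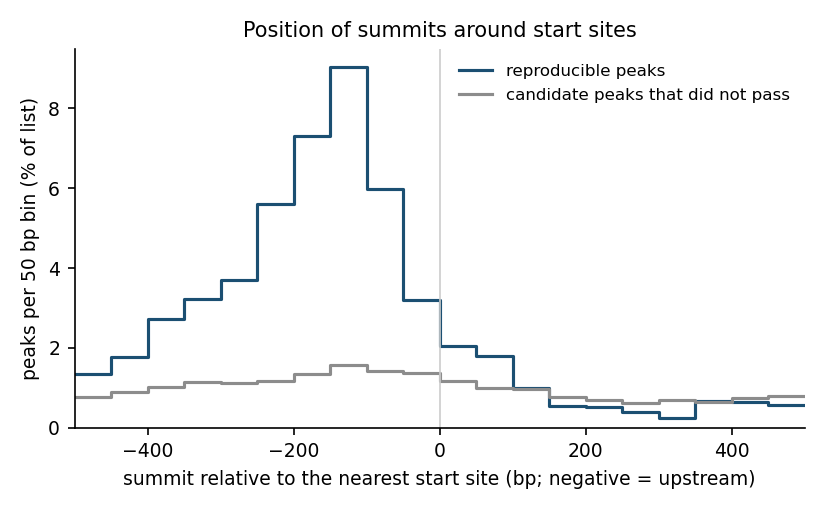
Position of summits relative to the nearest annotated start site (bp, x axis, negative values upstream), as the share of each list per 50 bp bin (y axis). Reproducible peaks have their highest bin from -150 to -100 bp, with 9.04% of the list, and candidate peaks that did not pass have 1.57% there.

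Among peaks within 500 bp of a protein-coding start site, the highest was at px (plexus, FBgn0003175), a wing-vein gene, at 2R 22514098 to 22514503 with a signal of 1207.5. Next came Tina-1 at 2R 24942377 to 24942770 (signal 1127.77) and CG14100 at 3L 19590435 to 19590791 (signal 1069.39). The 25 strongest such peaks ended with mRpL41 at a signal of 821. Named by the gene with the nearest start site, the others in order of signal were at CG1888, CG18428, Fhos, CG31145, Hrd3, bin3, Gapdh2, Fkbp14, CG1602, larp, Atf3, gish, RapGAP1, PIG-F, l(2)k01209, Pal1, CG1635, Sox14, Ugalt, mRpS10 and chn. Those at CG1888, Fhos, bin3, larp, l(2)k01209, Sox14 and chn lay 260 to 325 bp from the start site, beyond the 250 bp of a promoter peak. Some of these peaks also lay within 500 bp of a start site of a further gene, eIF4EHP at CG18428, PTPMT1 at Hrd3, PIG-G at CG1602, Lon at PIG-F, Pdrg1 at Pal1 and Art3 at mRpS10. Gapdh2 encodes a glycolytic enzyme, Hrd3 an endoplasmic reticulum degradation factor, and Atf3, Sox14 and chn encode transcription factors. All 25 were present in both replicates, at ranks from 7 to 57 in replicate 2 and from 7 to 67 in replicate 3.

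Several of the strongest peaks of the whole set were away from start sites. The peak of highest signal (2409) lay at 2L 6612414 to 6612941 in an intron of CG11050, 1016 bp from its nearest protein-coding start site. The next was at 2L 480884 to 481307 in an intron of ush, which encodes a Friend of GATA cofactor, with a signal of 1801 and cbt as the nearest start site. An intron of Trl, which encodes GAGA factor, held the peak at 3L 14759290 to 14759748 (signal 1598). A non-coding RNA gene, lncRNA:Vinr, held the peak at X 12750824 to 12751635 in an exon (signal 1413). The peak at 2R 21703202 to 21703694 lay in an intron where HmgZ and HmgD overlap (signal 1161). HmgZ and HmgD encode HMG-box chromosomal proteins.

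Pericentric heterochromatin and the Y chromosome held few or no reproducible peaks. Only 28 of the 2942 lay in the pericentric parts of arms 2L, 2R, 3L, 3R and X, against 378 predicted from sequence length, a ratio of 0.074 (95% Clopper-Pearson interval 0.049 to 0.107, exact binomial test, adjusted p = 4.63e-131 over 8 regions). The Y chromosome held 0 against 73.2 predicted (upper limit of the ratio 0.0504, exact binomial test, adjusted p = 5.64e-32). The predictions from length were not corrected for the copy number of X and Y, which in embryos of mixed sex is below that of the other chromosomes. Candidate peaks that did not pass were also sparse, with 1 on Y against 673 predicted and 555 in pericentric heterochromatin at a ratio of 0.160, and reads are hard to place in repeated sequence. On Y, with 0 reproducible and 1 candidate peak, the comparison of these lists could not detect a difference (Fisher's exact test, adjusted p = 1). In pericentric heterochromatin reproducible peaks were less frequent than candidate peaks (odds ratio 0.459, Fisher's exact test, adjusted p = 4.55e-05), a comparison added after seeing the data. Over whole arms, pericentric parts included, ratios lay between 0.988 on X and 1.12 on 2L, and of the 5 large arms only 2L passed (567 peaks, exact binomial test, adjusted p = 0.0070). From replicate 2 alone 3L passed as well (ratio 1.09, adjusted exact p = 0.0334). Without the pericentric parts, an alternative added after seeing the data, 2L was at 1.02 and did not pass (adjusted exact p = 0.620), and X was below the number predicted (496 peaks, ratio 0.884, interval 0.814 to 0.958, exact p = 0.0125 adjusted over 6 regions). Candidate peaks that did not pass had a ratio of 0.885 on that part of X. The small chromosome 4, which is largely heterochromatin-like yet carries active genes, held 21 peaks against 28.6 predicted (ratio 0.735, interval 0.455 to 1.12, adjusted exact binomial p = 0.299). Against the euchromatic parts alone it was 0.628 (adjusted exact p = 0.0583). From replicate 3 alone the ratio over whole arms was 1.01, and from replicate 2 alone it was 0.525 and passed (adjusted exact p = 0.0163). Candidate peaks that did not pass were 2.37 times as many on chromosome 4 as predicted from whole arms and 2.05 times as many as predicted from euchromatic parts, with 624 peaks, and reproducible peaks were there less often than candidate peaks (odds ratio 0.305, adjusted Fisher's exact p = 1.53e-09), a comparison added after seeing the data.

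Cytoplasmic ribosomal protein genes stood out among the bound promoters. Of 13945 protein-coding genes, 1689 (12.1%) had a reproducible peak within 500 bp of a start site. Genes for cytoplasmic ribosomal proteins, the protein part of the translating ribosome, had one in 47 of 85 cases (55.3%) against 11.8% of other genes (odds ratio 9.2, two-sided Fisher's exact p = 2.78e-20 adjusted over 31 lists). Among them were RpS27 (signal 360), RpL34b (317) and RpS10b (312), whose peaks were all weaker than the 25 strongest within 500 bp of a start site. None of the other 30 lists was above other genes after adjustment. With replicate 3 alone, 6 lists passed as above other genes, which were the Polycomb, trithorax, insulator, cytoplasmic and mitochondrial ribosomal protein and cell cycle lists, and with replicate 2 alone 1 list passed.

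Chemoreceptor, cuticle protein and histone genes lacked reproducible peaks within 500 bp of their start sites. None of 179 chemoreceptor genes, 117 cuticle protein genes or 111 replication-dependent histone genes had one, against 12.3%, 12.2% and 12.2% of other genes (adjusted Fisher's exact p = 2.45e-09, 4.82e-06 and 8.54e-06). Within 1000 bp, 2 chemoreceptor and 2 cuticle protein genes had a peak, and both lists were still below other genes (adjusted Fisher's exact p = 1.38e-08 and 4.99e-05). Within 500 bp, upper Wilson limits of the shares of these lists were 2.10%, 3.18% and 3.35%. The candidate list reached 6 chemoreceptor genes, 11 cuticle genes and 0 histone genes, so the histone genes, which lie in a repeated array, were absent from both. How reads were placed in repeated copies is not given in the sources used here. The histone result can therefore not be told from a lack of placed reads and does not inform on binding. Its Fisher's exact test also counts the copies of the array as separate genes. Chemoreceptor and cuticle genes did not pass when the comparison was limited to genes with a candidate peak (adjusted Fisher's exact p = 0.725 and 0.315). Their shares stayed at 0 there, and the 6 and 11 members left gave the test little power. Members of these lists lie in clusters. With list membership rotated along the gene order, an alternative added after seeing the data, the adjusted p-values were 0.00148 for ribosomal protein, chemoreceptor and cuticle genes and 0.0111 for histone genes.

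**Figure D4:**
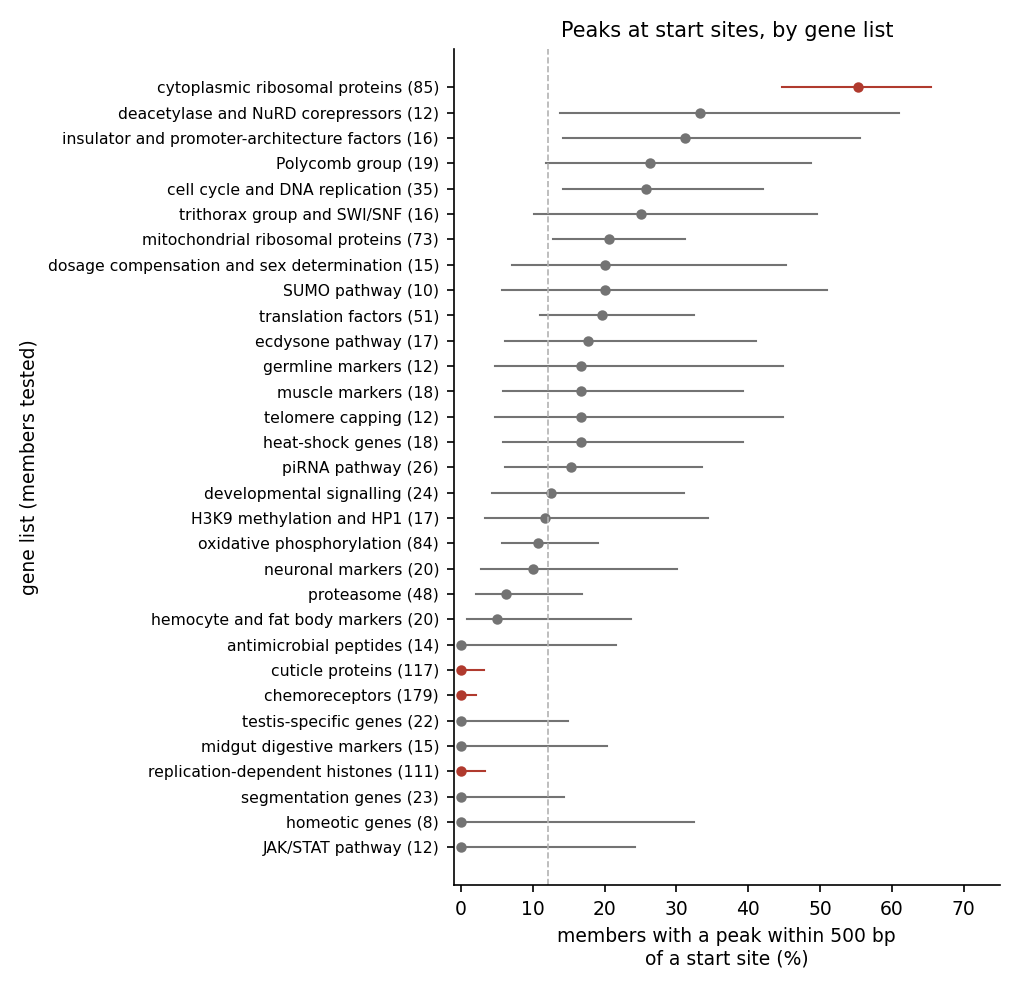
Share of members of each of the 31 gene lists with a reproducible peak within 500 bp of a start site (%, x axis), with 95% Wilson intervals and the number of members in brackets. The dashed line is the share over all genes, 12.1%, and red marks the 4 lists past an adjusted p of 0.05, cytoplasmic ribosomal proteins at 55.3% and 3 lists at 0.

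Genes of chromatin regulation had peaks at shares that did not pass after adjustment. Among regulators of the deacetylase and NuRD class 4 of 12 had a peak, including the corepressor gene gro (signal 452) and Sirt1 (317), and among insulator and promoter-architecture factors 5 of 16, including Chro (726) and Cp190 (642). Polycomb genes had 5 of 19, with ph-p (701) and E(z) (507) the strongest. Trithorax and SWI/SNF genes had 4 of 16, with brm (444) and Trl (281). The adjusted Fisher's exact p-values of these lists were 0.185, 0.185, 0.243 and 0.302. At Sirt1 the nearest replicate 3 summit, in an overlapping peak, lay 130 bp away, beyond the 100 bp of a match. Mitochondrial ribosomal protein genes had 15 of 73, led by mRpS10 (824) and mRpL41 (821), and cell cycle and DNA replication genes 9 of 35, led by Cdk1 (380) and RnrS (306), both with an adjusted p of 0.185. Without adjustment 5 lists passed as above other genes and 3 as below. Among the 1471 strongest peaks the cell cycle list passed too, with 8 of 35 genes (adjusted Fisher's exact p = 0.0222). From replicate 3 alone the trithorax list had 7 of 16.

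Genes of the SUMO pathway, to which Su(var)2-10 belongs, and of H3K9 methylation and the piRNA pathway did not differ detectably from other genes. In the SUMO pathway 2 of 10 genes had a peak, Uba2 (a subunit of the SUMO-activating enzyme, 3L 8127709 to 8128244, signal 355) and Sumo (the modifier itself, 2L 6967620 to 6968155, signal 245). Of 17 genes of H3K9 methylation and HP1, row (signal 276) and wde, which encodes a cofactor of a histone H3K9 methyltransferase (220), had a peak. Of 26 piRNA genes 4 had one, papi (431), piwi (230), cuff (212) and mino (182). At piwi the replicate 3 list had no summit within 100 bp, and its nearest, in an overlapping peak, lay 120 bp away. Adjusted Fisher's exact p-values were 0.666, 1 and 0.707. From replicate 3 alone the SUMO list had 4 of 10 and the H3K9 list 4 of 17, and neither passed (adjusted exact p = 0.0869 and 0.422). Su(var)2-10 (FBgn0003612, 2R 9116122 to 9122000) had no reproducible peak at its own start sites. A peak at 2R 9121902 to 9122437 (signal 607, rank 111 of 2942) covered the 3' end of the gene, and its summit lay 45 bp from the start site of the neighbouring gene GstE13.

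The remaining lists did not pass, whether their share was above or below the 12.1% of all genes. Translation factors had 10 of 51, with eIF4EHP (signal 1002, the same peak as at CG18428) and eIF6 (516) the strongest, oxidative phosphorylation 9 of 84 with ND-ASHI (293) and ND-MWFE (277), and the proteasome 3 of 48, with Rpn5 (303) and Prosalpha6 (283). Ecdysone pathway genes had 3 of 17, led by Eip75B (449) and Hr78 (225), heat-shock genes 3 of 18, led by Hsp27 (350) and Hsp83 (262), and dosage compensation and sex determination genes 3 of 15, led by Sxl (348) and dsx (171). Telomere capping genes had 2 of 12, tefu (266) and ver (161), and germline markers 2 of 12, gcl (247) and orb (218). Developmental signalling genes had 3 of 24, led by spi (633) and N (140). Among tissue markers, 3 of 18 muscle genes had a peak, led by Tm1 (248) and sls (187), as had 2 of 20 neuronal genes, elav (639) and fne (143), and 1 of 20 hemocyte and fat body genes, apolpp (174). None of 23 segmentation, 8 homeotic, 12 JAK/STAT, 15 midgut, 22 testis-specific or 14 antimicrobial peptide genes had a peak. From replicate 3 alone 2 of 12 JAK/STAT genes and 1 of 20 neuronal genes had a peak, and from replicate 2 alone 6 of 18 heat-shock genes. For the lists from translation factors to antimicrobial peptides the adjusted Fisher's exact p-values ran from 0.289 to 1.

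Among 6 classes of non-coding genes, long non-coding RNA genes alone passed within 250 bp of the gene, with more peaks than at shifted positions. Of 1945 such genes 147 (7.56%) had a reproducible summit within 250 bp, against 70.5 ± 8.17 (SD) over 1000 shifts (two-sided permutation test, p = 0.0120 adjusted over 6 classes). The shifts do not keep the excess of peaks at start sites of any gene (37.0% against 7.51% after shifts). Whether long non-coding RNA genes exceed what that general excess brings was not tested. Genes for tRNAs had 4 of 290 against 3.34 ± 2.14, snoRNAs 2 of 269 against 3.28 ± 2.63, and miRNAs 2 of 260 against 3.17 ± 2.09. None of 32 snRNA or 99 rRNA genes had a peak, with 0.428 and 1.19 predicted by the shifts. The adjusted p was 1 for each of these classes. From replicate 2 alone 1 snoRNA and 1 miRNA gene had a peak. Within 1000 bp snoRNA genes passed as well, with 32 of 269 against 10.4 ± 6.40 (permutation test, adjusted p = 0.0300).

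Reproducible summits were AT-rich, and each of the tested consensus sequences but the short BEAF-32 core and the initiator was found at fewer than 10% of them. Mean GC content was 32.2% ± 0.172 (SE) in the 100 bp at the summit and 43.8% ± 0.186 centred 500 bp away towards higher coordinates, while candidate peaks that did not pass went from 39.1% to 41.9%. Both promoter peaks (31.0%) and other reproducible peaks (32.9%) had the low value. The GC profile was examined after the data had been seen. Against the flanks of the same peaks, the DNA replication-related element TATCGATA was found within 100 bp of the summit in 61 of 2942 peaks (2.07%) against 0.714% (odds ratio 2.95, two-sided Fisher's exact p = 3.1e-07 adjusted over 17 motifs). By the same exact test, Ohler motif 7 (odds ratio 1.92, adjusted p = 3.14e-06), Ohler motif 6 (3.73, p = 0.0085), the Su(Hw) sequence (2.08, p = 0.0085), the TATA box (1.77, p = 7.95e-10) and the BEAF-32 core (1.17, p = 0.0074) were also above the flanks. The GAGA sequence bound by GAGA factor and Clamp (0.529, p = 2.43e-09), the Pho sequence (0.626, p = 2.43e-09) and CAGCTG (0.715, p = 0.000164) were below by the exact test. From replicate 2 alone the Su(Hw) sequence (1.46, exact p = 0.222) and the BEAF-32 core (1.08, exact p = 0.246) did not pass, and from replicate 3 alone CAGCTG (0.855, exact p = 0.0861) did not. The other 8 motifs, those of M1BP, Zelda, Stat92E, CTCF, TFIIIC, GATA factors and Twist and the initiator, did not pass. In windows of 200 bp to each side the M1BP (2.49, adjusted exact p = 3.58e-06) and TFIIIC sequences (10.0, from 5 peaks and 1 control window, adjusted exact p = 0.0378) passed as above.

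Several motif results turned or were lost with another control or window. Against candidate peaks matched for GC content, an alternative added after seeing the data, the DNA replication-related element (odds ratio 1.73, Fisher's exact test, adjusted p = 0.0088) and Ohler motif 7 (2.13, adjusted p = 4.71e-07) stayed above and the Pho sequence (0.794, adjusted p = 0.0114) below. GAGA (1.63, exact test, adjusted p = 0.00105) and CAGCTG (1.38, adjusted p = 0.0031) turned from below to above, and the TATA box (0.907), Ohler motif 6 (0.928), the Su(Hw) sequence (1.14) and the BEAF-32 core (1.10) no longer passed. For promoter peaks against promoter candidates none of the DNA replication-related element (1.20), Ohler motif 7 (1.35) and the Pho sequence (0.791) passed (adjusted exact p = 0.476, 0.136 and 0.181), while the TATA box was above (1.41, adjusted exact p = 0.0364) and the initiator below (0.724, adjusted exact p = 0.0103). In windows of 50 bp to each side the DNA replication-related element (1.93), Ohler motif 7 (1.55), Ohler motif 6 (3.00) and the BEAF-32 core (1.07) did not pass against the flanks (adjusted exact p = 0.0645, 0.0810, 0.199 and 0.438). In windows of 200 bp the Su(Hw) sequence (1.40), GAGA (0.990) and CAGCTG (1.04) did not pass (adjusted exact p = 0.175, 0.978 and 0.735). Against all candidate peaks Ohler motif 6, the Su(Hw) sequence, the BEAF-32 core, GAGA and CAGCTG did not pass (adjusted exact p from 0.0756 to 0.783). Among the 1471 strongest peaks Ohler motif 6 (2.67) and the Su(Hw) sequence (2.13) did not pass against the flanks (adjusted exact p = 0.334 and 0.0631).

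**Figure D5:**
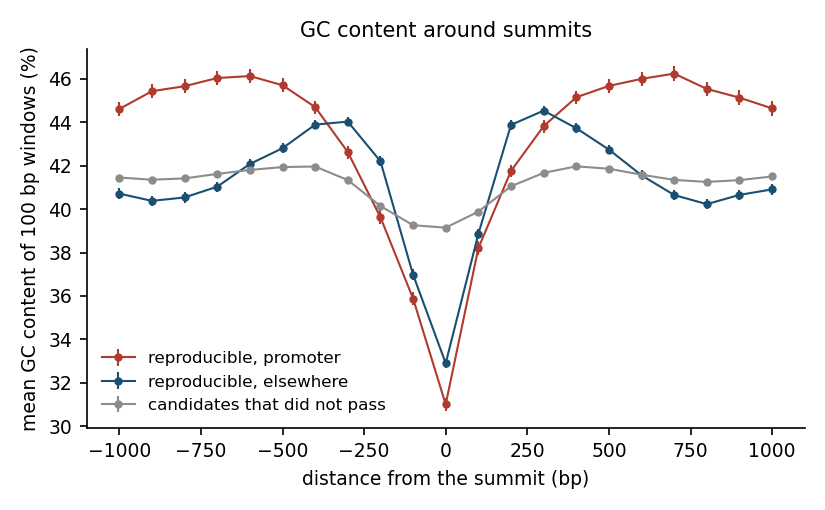
Mean GC content (%, y axis) of 100 bp windows by distance from the summit (bp, x axis), with standard errors over peaks, for 1089 promoter peaks, 1853 other reproducible peaks and 27058 candidate peaks that did not pass. At the summit the means are 31.0%, 32.9% and 39.1%.

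Soft-masked sequence, which holds interspersed repeats and low-complexity DNA, contained 28.04% of reproducible summits against 20.1% ± 0.953 (SD) after circular shifts (two-sided permutation p = 0.002, the smallest the shifts can give). Candidate peaks that did not pass had 19.8%. Annotated transposable elements went the other way. They held 0.170% of reproducible summits against 5.83% ± 0.753 after shifts (permutation p = 0.002, again the smallest possible). Candidate peaks had 1.19% against 6.15% after shifts. The shifts moved summits over whole arms, pericentric parts included, where peaks were sparse. Shifts within euchromatic parts alone were not run. A lack of peaks in annotated elements can therefore not be told from the lack in pericentric heterochromatin. The comparison with annotated elements was added after seeing the data, and peak calling at repeated copies depends on how reads were placed, which is not given in the sources used here.

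On the older dm3 build the authors' filter passed 2595 peaks, against 2942 on dm6, and the pooled list held 26751 candidate peaks. Replicate agreement there was 60.9% among the best 2595 peaks. Shares per arm were close on both builds, with 19.1% and 19.3% on 2L, 23.3% and 23.2% on 3R, and 0.771% and 0.714% on chromosome 4 for dm3 and dm6. On dm3, 1 peak lay on the separately assembled heterochromatic part of 2R.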

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

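Samples could not be paired because the study has 1 group. Over 231 comparisons of 34 results with an alternative, 173 kept their direction and their side of the threshold, 34 lost the threshold or fell in count, 7 gained it or rose and 17 turned in direction. The cause of the changes below was not tested except where it is given. Replicate agreement (33.7% to 69.9%), the promoter share (13.1% to 64.5%) and the sparsity of pericentric heterochromatin (ratios 0.040 to 0.114, and odds of 0.459 against candidate peaks) passed under every alternative run. The alternatives added after seeing the data are named in the description of the processing.

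With each replicate alone, the chromosome 4 ratio ranged from 0.525 to 1.01, arm 2R from 0.940 to 1.01, arm 3R from 0.988 to 1.01, arm X from 0.955 to 1.02, and lists above other genes from 1 to 6. With the 1471 strongest peaks, X was at 1.00, lists above other genes numbered 2, and genes with a peak numbered 1040 by construction. The signal difference between promoter and other peaks was 0.0768 there, in a subset itself chosen by signal. Over euchromatic parts only, 2R was at 1.07, since the length compared no longer held the pericentric parts. Against candidate peaks the odds on chromosome 4 were 0.305. With genes limited to those with a candidate peak, 0 lists were below other genes, and the histone list could not be tested because it had no such member. The chemoreceptor and cuticle shares stayed at 0, but with 6 and 11 such members the test had little power. Non-coding classes that passed numbered 2 at 1000 bp. Soft-masked repeats were above shifts, and annotated transposable elements below, at 0.170%.

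Motif results depended on the window and on the control. Motifs above their control numbered 6 against flanks, 4 among the 1471 strongest peaks, 2 in windows of 50 bp and 7 in windows of 200 bp to each side, 3 against candidate peaks, 4 against GC-matched candidates and 1 for promoter peaks against promoter candidates. Motifs below numbered 3 against flanks and 1 in windows of 200 bp to each side, against candidate peaks, for promoter peaks and against GC-matched candidates, which was Pho except for promoter peaks, where it was the initiator (0.724). Odds ratios turned against GC-matched candidates for motif 6 (0.928), CAGCTG (1.38), GAGA (1.63) and the TATA box (0.907). For promoter peaks they turned for motif 6 (0.710), CAGCTG (1.04), the Su(Hw) sequence (0.997) and the BEAF-32 core (0.967). CAGCTG was at 1.04 in windows of 200 bp to each side, and GAGA at 1.22 against all candidate peaks.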

Other observations

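All comparisons in this part were chosen after seeing the data, those of chromosome 4 before their own results were seen and those of ribosomal protein genes and 8-base sequences after. Many of the bound promoters had start sites of both strands nearby. Of the 1089 promoter peaks, 574 (52.7%, 95% Wilson interval 49.7 to 55.7) had annotated start sites of both strands within 500 bp of the summit. Candidate promoter peaks that did not pass had them in 923 of 3103 cases (29.7%), an odds ratio of 2.63 (two-sided Fisher's exact p = 6.36e-41). Away from promoters the mean GC content of reproducible peaks was 32.9% at the summit, 44.5% centred 300 bp away towards higher coordinates and 40.2% at 800 bp. The euchromatic arms had a mean of 42.6%, so the sequence at 300 bp was only slightly above it and the main feature was the low value at the summit.

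Sequences containing ACAGTG or its reverse complement were among those most in excess around the summits, in 3 of the 6 sequences that led a search. The search for 8-base sequences took arms 2L, 3L and X, with candidate peaks matched for GC content within 50 bp and 200 bp of the summit as control, and on arms 2R, 3R and 4, of which an unmatched count had been seen before, all 6 were above the matched control, among them CACAGTGG in 8.14% of 1057 regions against 2.23% (odds ratio 3.88, Fisher's exact p = 7.24e-13 adjusted over 6). The sequence that led the search, CAACACTG, gave an odds ratio of 2.94 there (exact p = 8.4e-06), which argues against GC content as the whole source, although 4 of 200 reorderings of its bases gave as much, as did 4 of 200 for ACAGTGGG with every overlapping peak counted. Over 1000 bp from any start site CAACACTG gave 2.31 (interval 0.660 to 8.39, exact p = 0.144), and within promoters 1.42 (interval 0.839 to 2.40, exact p = 0.198). It did not pass in either, and whether it goes with promoters as such stays open, a reading made stricter after the first value was seen. Over 1000 bp from start sites CACAGTGG (3.48), CACTGTGC (2.72) and ACAGTGGG (4.01) passed (adjusted exact p = 0.000102, 0.00136 and 0.000102). AACAGCTG (1.81) and CTCTCTGC (1.58) did not pass there (adjusted exact p = 0.291 and 0.327). With every overlapping peak counted, as in the search run before, ACAGTGGG led and gave 3.74 and, over 1000 bp from start sites, 3.05 (exact p = 8.81e-12 and 0.000126), and no biological explanation was tested.

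Candidate peaks that did not pass were in excess on chromosome 4, where they numbered 624, and the full lists of replicates 2 and 3 held 2.23 and 2.00 times the number predicted from length. Chromosome 4 is AT-rich (35.3% GC against 42.6% in the euchromatic arms), and summits were AT-rich, yet the GC content of 1 kb bins predicted 353 peaks, leaving a ratio of 1.77. Segments of the same length on other arms had ratios up to 1.49 (central 95% of 83 segments 0.631 to 1.40), which argues against base composition as the whole source. Of the lower-ranked replicate 2 peaks on chromosome 4, 28.9% had a replicate 3 summit within 100 bp, against 8.61% ± 1.09 (SD) after shifts. The share on the large arms was 27.97%, within the 95% Wilson interval of the chromosome 4 share (25.5 to 32.5). Not all of these peaks were thus chance calls in 1 replicate. An excess made only of unmatched calls would have lowered the share on chromosome 4. The excess therefore lay among matched and unmatched peaks, which argues against chance calls in 1 replicate as its whole source. Shifts of these peaks were not run for the large arms, so the matched excess was not corrected for matches by chance. A broad, low level of Su(var)2-10 or a property of the chromatin that both replicates share, such as its fragmentation, may underlie the excess, and no control profile was used here to separate these.

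Ribosomal protein promoters were bound far more often than those of other broadly expressed genes. Against the 4 lists of mitochondrial ribosomal proteins, proteasome, translation factors and oxidative phosphorylation together (37 of 256 genes, 14.5%), the odds ratio was 7.32 (Fisher's exact p = 1.11e-12). The ribosomal list had been picked as the highest of the 31, and the shares of the 4 lists had been seen. The p-value is therefore no independent support. The shares show only that broad expression, as in those 4 lists, did not by itself go with a share as high as 55.3%. Genes drawn to match in number of annotated start sites had a peak in 14.8% of cases, with 95% of 10000 draws between 8.24% and 22.35% against 55.3% observed, which argues against the number of start sites. Very high transcription, which can raise the recovery of chromatin in any immunoprecipitation, may still account for it and was not tested, since expression levels were not used here. No biological explanation was tested for this or for chromosome 4, since there is 1 group.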
